A study of Cucumis melo with 4 samples.

How the data were processed

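The series holds RNA-seq of melon (Cucumis melo) plants of 4 sex types, with 1 library for each. Monoecious plants bear male and female flowers, gynoecious plants female flowers only, hermaphrodite plants bisexual flowers only, and andromonoecious plants male and bisexual flowers. Per the labels' protocols, tissue was taken at 4 stages: true leaves at the 2-true-leaf stage, axillary buds and fresh leaves 1 week after transplanting, flower buds under 2 mm, and flower buds before flowering. RNA was extracted separately from recombinant inbred lines and mixed in equal amounts into a bulk for each sex type. Each library therefore averages over lines and tissues, and no sex type has a second library. The hermaphrodite library was sequenced on another flow cell than the other 3, per the labels.

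The authors' processed file for each library lists RPKM (reads per kilobase of transcript per M reads) for 76260 assembled unigenes, that is, transcripts assembled from the reads. The aligner and the assembler are not given in the sources used here. For 11737 unigenes the files name a melon coding sequence (CDS) and its product, with 11152 distinct CDS in all. A deposited table gives the percent identity and the length of each BLAST match between unigenes and melon CDS. The median match was 264 nt long, and 22% were under 100 nt. A unigene is called well matched here when its match had at least 95% identity, covered at least 100 nt and 30% of the unigene, and named a described product. This criterion was chosen after the BLAST table was seen, and 4003 unigenes met it. The CDS identifiers were looked up in a RefSeq gene table of assembly USDA_Cmelo_AY_1.0, where 0 of them occurred, so no coordinates are given. The authors also deposited raw read counts beside RPKM for genes of 4 comparisons and of 2 lists for the loci a and g, with log2 ratios, p-values and false discovery rates. Per the file headers, an RPKM of 0 in these tables stands in the ratios as a small constant, taken here as 0.001. 8 columns of per-library RPKM in the locus tables were not used.

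In the sample labels AAGG stands for monoecious plants and AAgg for gynoecious ones, while aaGG is given to the hermaphrodite and aagg to the andromonoecious library. The headers of the deposited locus tables exchange the last 2 and give andromonoecious aaGG and hermaphrodite aagg, as in the usual genetics of melon. Libraries are named by sex type here, and the allele of g is called "labelled" where it follows the sample labels.

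Because the library totals stand in the table headers, whole reads could be recovered from RPKM. For each unigene, the shortest length between 200 and 20000 nt was taken that gave whole reads in all 4 libraries within the rounding of the deposited RPKM. This worked for 100% of unigenes. On 1049 unigenes with length and counts in the authors' list for gynoecious against monoecious, 996 (94.9%) had the same length and the same counts in all 4 libraries, and for the others the listed length was up to 4 times the recovered one. On 2000 simulated unigenes the reads of 96.6% were recovered. Recovered reads made up 98.2 to 98.3% of the library totals.

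The design fixed before the data were examined assumed counts and edgeR, with limma where files hold only RPKM, so limma 3.58.1 on log2(RPKM + 1) is the main test of the 3 ways to set 2 libraries against 2: the a locus, the labelled g locus, and sex types with male flowers against those without. Fold changes on this scale understate those of low unigenes. Unigenes passing edgeR's filterByExpr (minimum count 10) were tested, 49238 in all, with Benjamini-Hochberg adjustment at 0.05. With 2 libraries a side, the spread holds the other locus, any interaction and library noise, and p-values measure only the spread between these 4 bulks. Single libraries were compared without a test, by log2 ratios of TMM-scaled reads (edgeR 4.0.16, prior count 1), counting unigenes with at least 50 reads in the pair and a ratio of at least 4-fold. Intervals are exact binomial (Clopper-Pearson) at 95% and cover counting error only. For a split, the fold and its interval rest on reads summed over the 2 libraries of each side. They do not show how far the libraries of a side differ, and 1 library can dominate a sum. A fold against 0 reads is a lower bound against a floor of 3 reads over the group. Correlations of log2 ratios were taken over unigenes with at least 50 reads in total. A count of unigenes that set 1 or 2 libraries at least 4-fold apart from all others (at least 100 reads in total) was added after the data were seen.

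The 28 gene lists were fixed before the data were examined, by words in the annotation: ethylene synthesis, ethylene response, auxin, gibberellin, cytokinin, brassinosteroid, abscisic acid, jasmonate, floral MADS, WIP zinc finger, pollen and anther, pectin enzymes, lipid transfer, fatty acid and cutin, cell cycle and histones, meiosis, photosynthesis, heat shock, defence, flavonoid, sugar transport and cleavage, expansins and xyloglucan enzymes, ribosomal proteins, MYB and bHLH factors, YABBY and homeobox factors, transposon-related, virus-related, and phloem and sieve tube. For a pair, a list's median log2 ratio was placed among 10000 random lists of annotated unigenes matched on expression in 20 bins, and lists with at least 5 unigenes of 50 reads or more were tested. A list is said to stand apart outside the percentiles 2.5 to 97.5. For the splits, limma's camera (preset correlation 0.01, and estimated) and fry were used.

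Named genes were chosen by a rule fixed beforehand. ACC synthase and WIP zinc finger unigenes come first. Each split gives the 10 annotated unigenes with the largest called change per direction, or, where fewer than 5 were called, the 5 with the largest change among those with at least 100 reads whose libraries do not overlap. Each pair gives the 5 with the largest ratio in each direction at 100 reads or more, and each list that stands apart up to 4 members. The restriction to well matched unigenes was added after the data were seen, and the text gives a part of these genes. Other genes are named in the sentences that say so.

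Alternatives were other scalings (DESeq2 size factors, TMM, library totals), DESeq2 1.42.0 and edgeR on recovered reads, other filters, pseudocount 0.1, additive fits, leaving out each library, reads summed per CDS, other minimum reads, folds and prior counts, lists of at least 95% identity, and a stricter ratio for the authors' lists. On simulated reads for the a locus split, with 200 of 49238 unigenes changed, limma called 35% of those changed 8-fold and 100% of those changed 64-fold, with 7 false calls. For the gene lists in a pair of libraries (43347 simulated unigenes), 98% of lists shifted by 1 log2 unit and 6% of unchanged lists stood apart. The unigenes of these simulated lists varied independently, unlike those of real lists may. For the agreement of pairs (44849 simulated unigenes), a common a effect in every unigene, with counting noise only and no spread between libraries, gave r = 0.914. R 4.3.3, Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.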

Results

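Transcript levels were compared between bulked plants of 4 melon sex types, with 1 library each. The totals were 26.39 M reads for the monoecious, 26.09 M for the gynoecious, 27.04 M for the hermaphrodite and 25.51 M for the andromonoecious library. Between 66492 and 69811 of the 76260 unigenes had at least 1 read. The 10 unigenes with the most reads took 10.1% of the monoecious reads, 8.2% of the andromonoecious, 6.98% of the hermaphrodite and 5.89% of the gynoecious. Unigenes with a melon CDS held 22.7 to 23.9% of the reads, so most of the signal lies in unigenes without a name. Differences between single libraries have no replicate check, and all intervals cover counting error only.

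The sex types differ at the loci a, known as an ACC synthase gene, and g, known as a WIP-type zinc finger gene, and such genes were looked at first. ACC synthase makes the precursor of ethylene. Unigene78052, annotated as ACC synthase 7, had 19 reads in the gynoecious library against 2 in the monoecious, 0 in the hermaphrodite and 1 in the andromonoecious. Unigene78228, annotated CMA101, had 21 gynoecious reads against 1, 8 and 6 in the same order. Unigene78536, a further ACC synthase, had 12 against 0, 0 and 2. All 3 were therefore highest in the gynoecious library, at few reads. The files do not name a unigene as the a or g gene, and the known a allele changes the protein, so these levels check no label. No unigene was annotated as a WIP protein of the zinc finger type. The WIP zinc finger words took up Unigene34680 and Unigene50033, annotated TRANSPARENT TESTA 1, which is a member of that family in Arabidopsis. The same words picked the WPP domain-interacting protein Unigene34177 and the WD repeat proteins Unigene60685 and Unigene70149, none annotated as a zinc finger protein. Unigene34680 (a match of only 74 nt) had 228 monoecious, 289 gynoecious, 329 hermaphrodite and 455 andromonoecious reads, and Unigene50033 had 62, 86, 67 and 86.

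The a locus comparison set the monoecious and gynoecious libraries (AA) against the hermaphrodite and andromonoecious (aa), a contrast on which both sources of genotypes agree. Of the named genes, the cold-induced plasma membrane protein Unigene33002 was 6.75-fold higher in aa (interval 6.20 to 7.36), with 2040 hermaphrodite and 2099 andromonoecious reads against 454 monoecious and 166 gynoecious. Para-aminobenzoate synthase Unigene33543, an enzyme of folate synthesis, was 25.6-fold higher in aa (13.3 to 56.7), with 84 and 144 reads against 9 and 0. The coleoptile phototropism protein Unigene25642 was 6.55-fold higher (5.59 to 7.71). On the AA side, the DNA repair protein XRCC1 Unigene34504 was 15.6-fold higher (11.4 to 22.1), mostly through 570 gynoecious reads against 63 monoecious, 19 hermaphrodite and 21 andromonoecious. Serine/threonine-protein kinase 36 Unigene4660 was 6.92-fold higher in AA (4.01 to 12.8).

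None of these named genes passed limma's test or edgeR's (adjusted p = 1), while with DESeq2 para-aminobenzoate synthase (adjusted p = 0.0156), the cold-induced protein (0.0238) and XRCC1 (0.0156) did. The test called 2 unigenes higher and 4 lower in aa. All 6 are uncharacterised or unannotated, and at most 2 in each direction are given by name. Unigene44707 had 2264 monoecious and 840 gynoecious reads and 0 in both aa libraries (log2 change -6.43 ± 0.57 SE, limma adjusted p = 0.012), and Unigene72225 had 504 and 1034 against 0 and 0 (-6.31 ± 0.53, adjusted p = 0.012). In the other direction, Unigene44708 had 2 and 0 reads in AA against 433 and 583 in aa (adjusted p = 0.0301), and Unigene45921 had 3 and 3 against 249 and 311 (4.63 ± 0.51, adjusted p = 0.0367). At an unadjusted p under 0.05 limma had 1408 of 49238 unigenes, fewer than the share of 0.05 that chance would give. edgeR on recovered reads called 0 (1012 at an unadjusted p under 0.05) and DESeq2 called 26. With TMM factors or DESeq2 size factors in limma, 3 unigenes lower in aa and 0 higher were called. limma called 537 without the monoecious library, 31 without the gynoecious, and 0 without the hermaphrodite (718 at an unadjusted p under 0.05) or the andromonoecious (551).

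The list of abscisic acid genes was higher in aa by camera (16 unigenes, median log2 change 0.32, adjusted p = 0.0116), and so was sugar transport and cleavage (25 unigenes, median 0.23, adjusted p = 0.0393). Neither held with an estimated correlation (adjusted p = 0.978 for both). fry, which asks whether a list moves on balance one way and does not compare it with other genes, gave adjusted p = 0.553 for both. No single member of either list was called, also when adjusted over the list alone (0 of 16 and 0 of 25). Only 6 of the 16 abscisic acid and 15 of the 25 sugar unigenes have a match of at least 95% identity. camera was not run on those alone.

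The labelled g locus comparison set the monoecious and hermaphrodite libraries (GG by label) against the gynoecious and andromonoecious (gg by label). FEI 1 Unigene6558, a receptor-like kinase known from root cell wall synthesis, was 7.56-fold higher in gg (5.95 to 9.73), with 290 gynoecious and 257 andromonoecious reads against 40 monoecious and 37 hermaphrodite. The leucine-rich repeat protein 40 Unigene7017 was 6.32-fold higher (5.01 to 8.07). Peroxidase 53 Unigene45838 was 5.94-fold higher in GG (5.19 to 6.82), with 760 and 795 reads against 27 and 219. Peroxisome biogenesis factor 10 Unigene71615 was 9.61-fold higher in GG (7.86 to 11.8), with 481 and 603 reads against 2 and 104. Malate synthase Unigene35217, an enzyme of the glyoxylate cycle, was 3.84-fold higher in gg (3.15 to 4.71), but through the 0 hermaphrodite reads, since the monoecious library had 128, the gynoecious 177 and the andromonoecious 285.

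limma called 0 unigenes for the labelled g locus, with 2531 of 49238 at an unadjusted p under 0.05, near the share of 0.05 that chance would give. The named genes had an adjusted p of 0.918 with limma. edgeR also called 0 (2192 at an unadjusted p under 0.05), and DESeq2 called 30, among them FEI 1 (adjusted p = 0.00172) and the leucine-rich repeat protein 40 (0.0134). limma called 13 without the gynoecious library, 6 without the hermaphrodite and 849 without the andromonoecious, the last a comparison of the gynoecious library alone with the monoecious and hermaphrodite. No list passed camera.

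Sex types that bear male flowers (monoecious and andromonoecious) were set against those that do not (gynoecious and hermaphrodite), the split that follows the g locus under the genotypes in the table headers. Gibberellin 3-beta-dioxygenase 1 Unigene18761, which makes active gibberellins, was 14.7-fold higher with male flowers (13.5 to 16.1) on summed reads. It had 4842 monoecious and 2240 andromonoecious reads against 519 gynoecious and 29 hermaphrodite. Its log2 change with limma was 4.22 ± 0.9 SE, a wider spread than the counting interval shows. REVOLUTA Unigene23, a homeobox-leucine zipper factor known for organ polarity and meristems, was 31.4-fold higher (23.0 to 44.0), with 428 and 704 reads against 29 and 12. Retinol dehydrogenase 12 Unigene13775 had 341 and 218 reads against 2 and 0, a ratio of 318 (87.5 to 2630). Retinol dehydrogenase 14 Unigene33602 had 117 and 107 against 1 and 0. The retrovirus-related polyprotein Unigene30330 was 45.8-fold higher (34.5 to 62.1).

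On the other side, the chloroplast NADP malate dehydrogenase Unigene35218 was 5.52-fold higher without male flowers (4.93 to 6.20), with 1487 gynoecious and 690 hermaphrodite reads against 110 and 237. The mitochondrial NADH dehydrogenase flavoprotein Unigene13637 was 11.4-fold higher (7.05 to 19.6), the nuclear GTP-binding protein Ran-3 Unigene32512 5.09-fold (4.36 to 5.97) and the heat shock protein binding protein Unigene44265 3.69-fold (3.49 to 3.91). For Ran-3 this came mostly through 840 gynoecious reads, with 253 hermaphrodite reads against 54 monoecious and 135 andromonoecious.

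limma called 1 unigene here, the uncharacterised Unigene54757, with 461 and 604 reads against 0 and 0 (log2 change 5.64 ± 0.43 SE, adjusted p = 0.0326). It had 4092 of 49238 at an unadjusted p under 0.05, above the share of 0.05 that chance would give, over unigenes that are not independent. edgeR called 0 (3296 at an unadjusted p under 0.05), while DESeq2 called 280, of them 215 higher with male flowers. REVOLUTA had an adjusted p of 0.357 with limma, 0.267 with edgeR and 1.49e-11 with DESeq2, and Gibberellin 3-beta-dioxygenase 1 had 0.556, 0.727 and 0.398. On the simulated a locus split DESeq2 made 42 false calls and limma 7 with 200 unigenes changed, and 2 and 0 with none changed. That simulation gave all unigenes the same spread and was not made for the male flower split, so it does not show how many of the 280 are false. Among the gene lists none passed camera. Adjusted over the list alone, limma called 2 of 11 gibberellin, 3 of 23 transposon-related and 2 of 26 heat shock unigenes, and 1 each of 35 cytokinin, 105 ribosomal protein, 69 MYB and bHLH, and 45 YABBY and homeobox unigenes, where 0 were called over all unigenes. limma called 352 without the hermaphrodite library, a comparison of the gynoecious library alone with both types with male flowers, 3 without the gynoecious and 0 without the andromonoecious (3859 at an unadjusted p under 0.05).

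**Figure D1:**
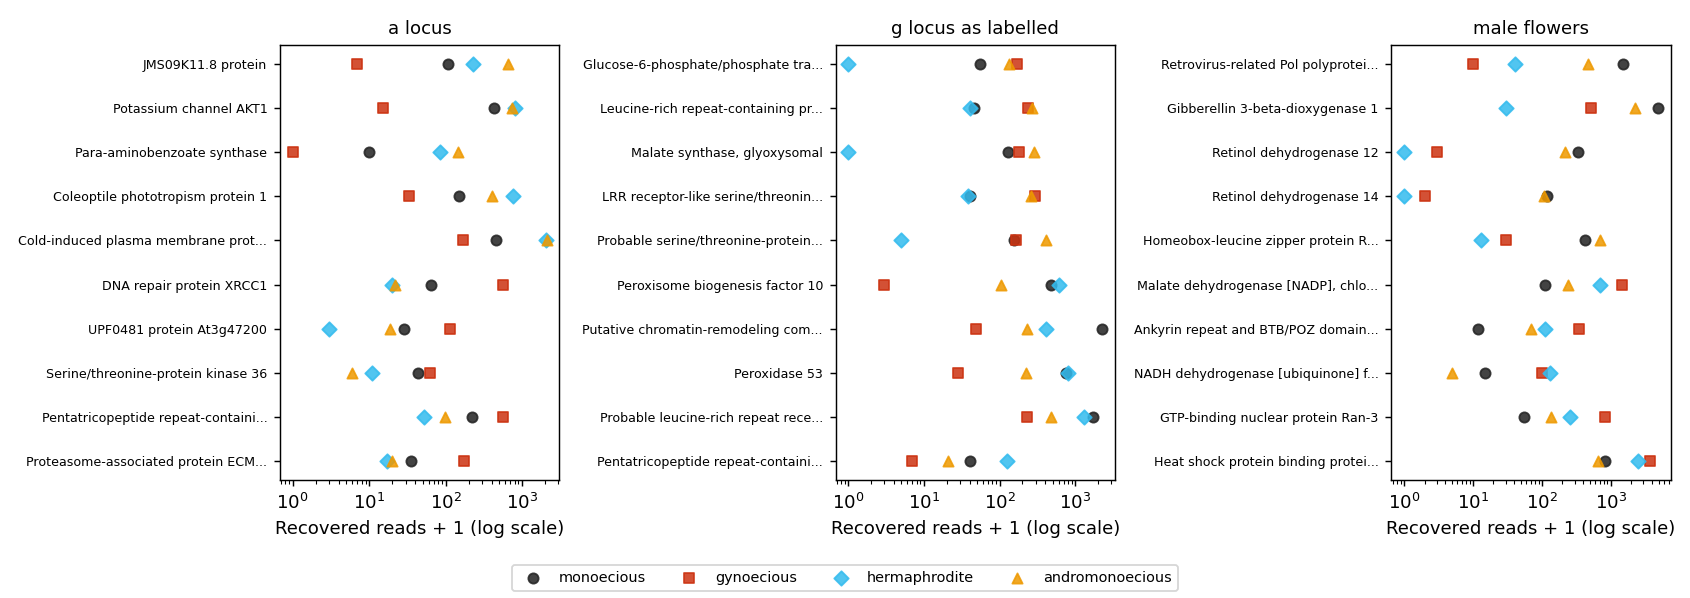
Recovered reads plus 1 (log axis) of the named genes of the a locus, the labelled g locus and the male flower comparison, 1 point per library. REVOLUTA had 428 and 704 reads in the monoecious and andromonoecious libraries against 29 and 12 in the others.

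Among 2445 well matched unigenes with at least 100 reads, the libraries of the 2 sides did not overlap for 997 (40.8%) in the male flower split, 891 (36.4%) in the labelled g split and 557 (22.8%) in the a split. Chance gives 33.3% for each, and the 3 shares add up to 100% by construction, so a higher share of one lowers the others. Asking for at least 4-fold between the closest libraries, over all unigenes with at least 100 reads, 137 unigenes followed the male flower split, 53 the labelled g split and 43 the a split. Of the 137, 121 were higher with male flowers. Among these were the NAC domain protein 74 Unigene59202 (113 monoecious, 14 gynoecious, 2 hermaphrodite and 93 andromonoecious reads) and the squamosa promoter-binding-like protein 16 Unigene21648 (47, 6, 8 and 47), both singled out after their values were seen.

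Pairs that share no library were also correlated across unigenes, which are not independent replicates. The log2 ratio of hermaphrodite over monoecious went with that of andromonoecious over gynoecious at Pearson r = -0.194 and Spearman rho = -0.222 over 44482 unigenes. That of andromonoecious over monoecious went with hermaphrodite over gynoecious at r = -0.094 (rho = -0.162). That of gynoecious over monoecious went with andromonoecious over hermaphrodite at r = -0.107 (rho = -0.065). These are not separate results, since by arithmetic the covariance behind the first equals the sum of the covariances behind the others. In the same order, 41.4%, 42.6% and 48.4% of unigenes had the same direction in both pairs. On simulated reads with a common a effect the first of these correlations was 0.914. That simulation gave every unigene an a effect and held counting noise only. It had no spread between libraries, so 0.914 is no expectation for these bulks.

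Single libraries differed most between gynoecious and monoecious, which had a 4-fold ratio for 4014 of 34821 unigenes (11.5%), 1747 higher and 2267 lower in gynoecious. Pheophorbide a oxygenase Unigene23756, an enzyme of chlorophyll breakdown, was 16.2-fold higher in gynoecious (13.8 to 19.3), with 2597 reads against 150. Anoctamin-10 Unigene7905 had 117 reads against 0, at least 36.5-fold higher. The cation/H(+) antiporter 4 Unigene929 was 18.6-fold higher (8.29 to 51.7). Lower in gynoecious were the phosphatidylinositol phosphodiesterase Unigene34347 (2 reads against 312) and the microtubule-severing katanin p80 subunit Unigene9778 (0 against 112, at least 39.8-fold lower).

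In this pair 4 gene lists stood apart. Cell cycle and histone genes were higher in gynoecious (78 unigenes, median log2 ratio 0.44, percentile 99.64), with 24 at least 2-fold higher and 10 at least 2-fold lower. They included cyclin-dependent kinase B2-2 Unigene44845 (831 reads against 109), cyclin-D3-3 Unigene22025 (7971 against 1328), cyclin-D5-1 Unigene24462 (157 against 24) and histone H4 Unigene21624 (221 against 23). Ribosomal protein genes were lower (107 unigenes, median -0.44, percentile 0.05), among them 40S S21-2 Unigene57505 with 15377 reads against 28438. Transposon-related genes were lower (23 unigenes, median -0.77, percentile 0.32), led by Unigene30330 with 9 reads against 1505. Cytokinin genes were lower (35 unigenes, median -0.53, under percentile 2.5), led by cytokinin-O-glucosyltransferase 1 Unigene44903 with 29 reads against 178, but the 13 with a match of at least 95% identity had a median of 0.01.

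Hermaphrodite and monoecious differed 4-fold at 1599 of 35176 unigenes. SPEECHLESS Unigene43918, the factor that starts the stomatal lineage, had 102 hermaphrodite and 2 monoecious reads, a ratio of 45.5 (12.3 to 381), and histone H4 Unigene21625 was 11.1-fold higher (8.45 to 14.8). Among the unigenes with no hermaphrodite read was the leaf glutamine synthetase Unigene48986 (202 monoecious reads, at least 75.4-fold lower), which assimilates ammonium in the chloroplast. Another was YUCCA6 Unigene19419 (148, at least 55.3-fold lower), an enzyme of auxin synthesis. Reads of a gene can also lie on another unigene, so a unigene without reads does not show a silent gene, here and in the other comparisons. The ubiquitin ligase PUB23 Unigene11469 had 4 reads against 652. Ribosomal protein genes were lower (107 unigenes, median -0.22, percentile 0.3). Flavonoid genes were higher (31 unigenes, median 0.42, percentile 98.5), with flavonoid 3'-monooxygenase Unigene48263 at 466 reads against 208, and so were abscisic acid genes (16 unigenes, median 0.57, percentile 98.73), which no longer stood apart with matches of at least 95% identity (6 unigenes, median 0.37, percentile 76.67).

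Andromonoecious and monoecious, which differ at a under the genotypes of the table headers, had 4-fold ratios at 1485 of 34156 unigenes. Kanadaptin Unigene55478 was 7.24-fold higher in andromonoecious (4.88 to 11.1) and cyclin-dependent kinase B2-2 Unigene44845 had 705 reads against 109. The MATE efflux protein Unigene31691 was 23.9-fold lower (11.9 to 56.1), acetyl-CoA carboxylase Unigene10786 of fatty acid synthesis 15.9-fold lower (9.61 to 28.2), and nitrate reductase Unigene38492 7.61-fold lower (4.59 to 13.4). Abscisic acid genes were higher (16 unigenes, median 0.87, percentile 99.92), 7 of them at least 2-fold and 0 at least 2-fold lower, though only 6 of the 16 have a match of at least 95% identity. Of the 6 receptor unigenes, PYL9 Unigene2352 had 809 reads against 440, PYL8 Unigene2351 had 61 against 25 and PYL2 Unigene57750 had 46 against 8, while PYL4 had 208 against 221 (Unigene49901) and 1555 against 2493 (Unigene49900), and PYL8 Unigene22246 had 97 against 168. All of these receptors but Unigene2352 and Unigene2351 rest on a match of only 44 nt. Of the hydroxylases that break abscisic acid down, Unigene19909 had 711 reads against 1252, Unigene22277 1308 against 548, Unigene31464 58 against 37 and Unigene40554 197 against 224. All of these receptors and hydroxylases but Unigene19909 were singled out after their values were seen. Sugar transport and cleavage genes were higher (25 unigenes, median 0.65, percentile 99.74), with sucrose synthase Unigene20028 at 807 reads against 280 and sucrose synthase 2 Unigene20029 at 443 against 210.

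Hermaphrodite and gynoecious differed 4-fold at 1999 of 35063 unigenes. The potassium channel AKT1 Unigene51104 was 55.3-fold higher in hermaphrodite (32.8 to 102), with 813 reads against 14. Malate synthase Unigene35217 had 0 hermaphrodite reads against 177 (at least 61.9-fold lower), the glucose-6-phosphate translocator Unigene39765 had 0 against 170 (at least 59.5-fold lower), and the leaf glutamine synthetase Unigene48986 had 0 against 188 (at least 65.8-fold lower). Cytokinin genes (35 unigenes, median 0.40, percentile 97.98) and abscisic acid genes (16 unigenes, median 0.64, percentile 98.9) were higher. Neither stood apart with matches of at least 95% identity (13 cytokinin unigenes, median 0.22, percentile 76.55; 6 abscisic acid unigenes, median 0.49, percentile 89.75).

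Andromonoecious and gynoecious differed 4-fold at 2534 of 34335 unigenes, 1782 of them higher in andromonoecious. Katanin p80 Unigene9778 had 207 reads against 0 (at least 79.7-fold higher) and the proteasome activator subunit 4 Unigene55649 had 136 against 0 (at least 52.3-fold higher). XRCC1 Unigene34504 was 23.5-fold lower (15.2 to 38.3) and nitrate transporter 1.7 Unigene64632 22.3-fold lower (8.45 to 83.4). Heat shock genes were lower (27 unigenes, median -0.50, percentile 0.89). YABBY and homeobox factors were higher (45 unigenes, median 0.41, percentile 99.02), with REVOLUTA Unigene23 at 704 reads against 29 and ATHB-15 Unigene31587, of the same family, at 188 against 44. Transposon-related genes were higher (23 unigenes, median 0.80, percentile 99.9).

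Andromonoecious and hermaphrodite differed least, with 4-fold ratios at 1225 of 34717 unigenes (3.53%). Higher in andromonoecious were Myb-like protein G Unigene3065 (227 reads against 0, at least 91.7-fold), the leaf glutamine synthetase Unigene48986 (334 against 0, at least 135-fold) and malate synthase Unigene35217 (285 against 0, at least 115-fold). Linalool synthase Unigene11217, which makes a floral scent compound, had 2 andromonoecious reads against 149, a ratio of 61.5 (16.7 to 512). Heat shock (27 unigenes, median -0.31, percentile 2.1) and flavonoid genes (31 unigenes, median -0.38, percentile 0.51) were lower, with chalcone synthase A Unigene50349 at 74 reads against 221. With matches of at least 95% identity the flavonoid list no longer stood apart (25 unigenes, median -0.33, percentile 3.3). Transposon-related genes were higher (23 unigenes, median 0.54, percentile 99.51).

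In all, 17 of the 144 combinations of 24 lists and 6 pairs stood apart, where 7.2 would by chance if the unigenes of a list varied independently. Unigenes of a list can vary together. The pairs also share libraries, so a single library can set a list apart in several pairs. The excess over 7.2 is therefore no test of the lists. None of the 6 pairs did so for 15 lists: ethylene synthesis, ethylene response, auxin, gibberellin, brassinosteroid, jasmonate, floral MADS, pollen and anther, pectin enzymes, fatty acid and cutin, meiosis, photosynthesis, defence, expansins and xyloglucan enzymes, and MYB and bHLH factors. With matches of at least 95% identity, defence genes stood apart in hermaphrodite over monoecious (34 unigenes, median 0.40, percentile 97.7). Single members of these lists still differed. The stamen and petal identity gene PMADS 2 Unigene20965 had 39 gynoecious reads against 88 monoecious, 74 hermaphrodite and 133 andromonoecious, and AGAMOUS Unigene21628, of stamen and carpel identity, had 204 monoecious, 109 gynoecious, 129 hermaphrodite and 90 andromonoecious reads. DEFICIENS Unigene45995, also of stamen and petal identity, had 10, 25, 18 and 0 in the same order. All 3 were singled out after their values were seen. Of the 4 lists too small to place, WIP zinc finger had 3 unigenes with at least 50 reads, lipid transfer 3, virus-related 1 and phloem and sieve tube 4. The virus-related word had picked a cellular helicase, and 1 of the 3 WIP unigenes was the WPP domain-interacting protein Unigene34177. Phloem filament protein Unigene48865 had 41 monoecious, 275 gynoecious, 168 hermaphrodite and 92 andromonoecious reads, and the lipid-transfer protein Unigene641 had 1276, 2347, 2198 and 1655.

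**Figure D2:**
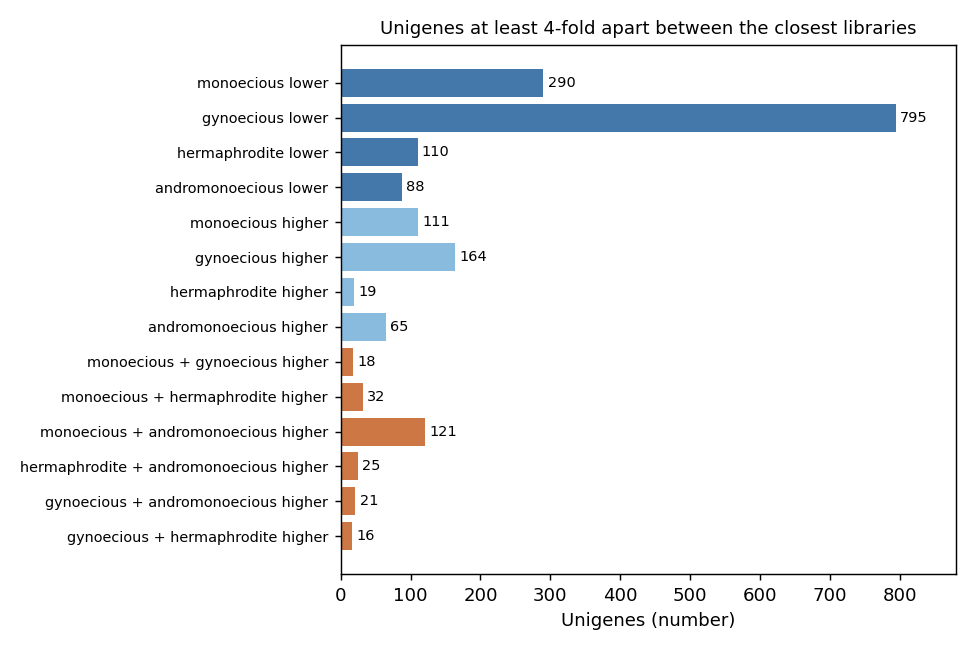
Number of unigenes with at least 100 reads in which 1 library, or 2 libraries, lie at least 4-fold from all others. The longest bar is 795 unigenes lower in gynoecious alone, and among the sets of 2 libraries 121 were higher in monoecious and andromonoecious.

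The authors' deposited tables list genes of 4 comparisons, each with an absolute log2 ratio of at least 2 and a false discovery rate of at most 0.001. The authors' deposited table for gynoecious over monoecious holds 1058 genes (586 higher, 472 lower), and the authors' deposited table for gynoecious over hermaphrodite 663 (286 higher, 377 lower). The authors' deposited table for monoecious over andromonoecious holds 610 (278 higher, 332 lower), and the authors' deposited table for hermaphrodite over andromonoecious 500 (261 higher, 239 lower). In the authors' deposited tables the ratio equals that of the RPKM values on its row, within 0.01, for 54.4 to 69.7% of genes. The authors' deposited table for the a locus holds 128 genes, which are the 128 shared by the lists of monoecious over andromonoecious and gynoecious over hermaphrodite, whatever the direction. It was chosen on these same libraries and is no independent evidence. Lists of those lengths would share 36.2 of 11152 CDS by chance if every CDS were equally likely to be listed. Only 8605 CDS had enough reads for limma's test of summed reads, so this number is likely too low. The overlap exceeded it in opposite directions (27 against 9.4 and 34 against 8.5) as well as in the same one (24 against 7.1 and 43 against 11.2). It is therefore no sign of an a effect. In the authors' deposited table for the a locus, 67 genes have the same direction in both comparisons (52.3%, Clopper-Pearson interval 43.3 to 61.2%) and 61 have opposite directions. Genes measured in the same libraries are not independent, so this interval and the next are likely too narrow. The authors' deposited table for the g locus holds 129 genes, again the full overlap, where 47.4 would be shared on the same assumption. In the authors' deposited table for the g locus, 77 have the same direction in gynoecious over monoecious and hermaphrodite over andromonoecious (59.7%, interval 50.7 to 68.2%). Both of these run from GG to gg under the genotypes of the table headers, whereas under the sample labels they run opposite ways, and the other 52 of 129 then share the direction of the labelled allele. 34 genes stand in both of the authors' deposited tables for the loci.

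**Figure D3:**
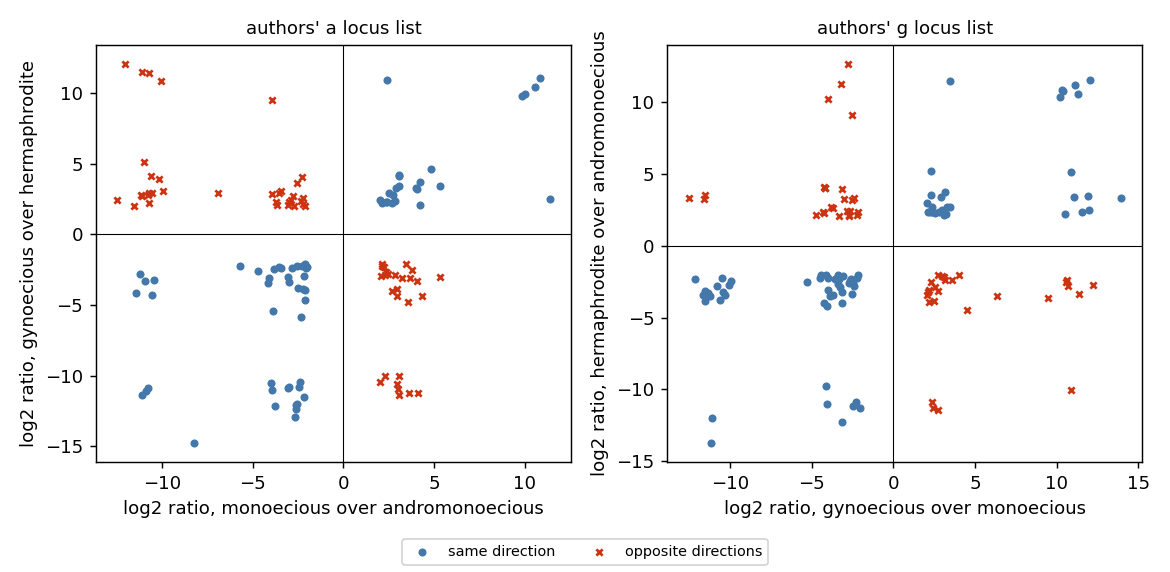
Log2 ratios from the authors' deposited tables for genes of the a locus list (first panel) and the g locus list (other panel), 1 point per gene, with the 2 comparisons of each locus on the axes. Blue dots have the same direction in both (67 and 77 genes) and red crosses opposite directions (61 and 52).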

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

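The tests of the flow cell, of exchanged genotype labels and on the authors' lists were chosen only after their results had been seen in part.

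In the authors' deposited table for the a locus, 61 of 128 genes move in opposite directions in the 2 comparisons the list rests on. In the authors' deposited table for the g locus 52 of 129 do, for gynoecious over monoecious and hermaphrodite over andromonoecious; under the sample labels these run opposite ways between the alleles, and the other 77 then go against a common g effect. These stood out as differences between groups, and the difference between the 2 effects of a gene was not tested. A ratio taken from another unigene than the values beside it is argued against as the whole cause, since 40.4% of the 52 genes whose ratio matches in both a locus comparisons (interval 27.0 to 54.9%) still have opposite directions. An a allele effect common to both comparisons is argued against for the list as a whole, because 52.3% have the same direction. The lists are full overlaps of gene lists taken without regard to direction. Their genes are not independent, so the interval given here is likely too narrow. What stays open is a response to a that depends on g, other variation between bulks and, under the sample labels, a plain g effect, since both a locus comparisons then also differ at g, in opposite ways.

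A labelled g difference of at least 8-fold, with opposite sign in the AA pair and in the aa pair, was found for 8 well matched unigenes, and 0 had the same sign in both; this was not tested. For example, the log2 ratio of gynoecious over monoecious was -3.93 for REVOLUTA Unigene23 and that of andromonoecious over hermaphrodite was 6.03. For Gibberellin 3-beta-dioxygenase 1 Unigene18761 these were -3.31 and 6.50. These unigenes belong to the wider pattern that more unigenes followed the male flower split (137) than the labelled g split (53) or the a split (43). Depth is argued against because the libraries held nearly equal numbers of recovered reads, 25.05 to 26.55 M. Thinning every library to 25.05 M reads therefore changed little, and 130 unigenes still followed the male flower split. In 1100 unigenes at least 4-fold lower in gynoecious than in monoecious and andromonoecious, the hermaphrodite library had a median log2 shift of -0.92 from the mean of those types. In the matching 809 unigenes chosen without the andromonoecious library, that library had -0.09 (difference of medians -0.83, bootstrap range -0.98 to -0.7). The bootstrap resampled unigenes, which are not independent, so its range does not cover variation between bulks. The larger set includes 119 of the 121 unigenes higher in both types with male flowers, so it is not separate from the pattern. The other flow cell stays open, since the hermaphrodite library alone was sequenced there and cannot be told apart from it. Exchanged genotype labels of the hermaphrodite and andromonoecious libraries stay open as well: gynoecious over monoecious correlated with hermaphrodite over andromonoecious at r = 0.107, which is the male flower pattern itself, and the a locus pairs under exchanged labels correlated at r = -0.094. Male flowers, a g allele effect under the genotypes in the table headers, and an interaction of the 2 loci under the sample labels predict the same split and remain open.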

How the results depend on the processing

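TMM factors and edgeR in the splits, the additive fits with the male flower or labelled g split, the settings for libraries that stand apart and the log2 ratio of 3 were chosen after seeing the data. With 2 bulks a side, the calls of the splits depended on the settings. For the a locus, against 6 calls by limma, DESeq2 size factors, TMM factors, a filter of 1 read and pseudocount 0.1 each gave 3, sums per CDS 2, DESeq2 26, edgeR 0, and the additive fit with the male flower split 28; leaving out 1 library gave 0 to 537, the highest without the monoecious library. For the labelled g locus, against 0, DESeq2 gave 30, and leaving out 1 library 0 to 849. For the male flower split, against 1, DESeq2 gave 280, edgeR, the filter of 1 read, sums per CDS, pseudocount 0.1 and the additive fit with the labelled g locus 0, the additive fit with the a locus 46, and leaving out 1 library 0 to 352. The highest of each range set the gynoecious library alone against 2 others, with that lone library assumed to vary like theirs. The cause of the other differences was not tested. In the order gynoecious, hermaphrodite and andromonoecious over monoecious, hermaphrodite and andromonoecious over gynoecious, and andromonoecious over hermaphrodite, the counts of 4-fold unigenes became 10902, 6983, 6545, 6764, 7246 and 5335 at a minimum of 10 reads, 1901, 449, 469, 826, 1130 and 337 at 200, 12746, 8186, 7482, 9501, 9601 and 7169 at 2-fold, and 771, 319, 291, 425, 562 and 254 per CDS, by construction; gynoecious against monoecious was highest in each. The correlations kept their sign: -0.128, -0.068 and -0.063 at a minimum of 10 reads, -0.256, -0.124 and -0.144 at 500, and -0.057 (andromonoecious over monoecious) and -0.147 (gynoecious over monoecious) per CDS. At a minimum of 500 reads, 33 unigenes followed the male flower split, 8 the labelled g and 12 the a split, and 72 were lower in monoecious alone, 347 in gynoecious, 25 in hermaphrodite and 13 in andromonoecious. With an estimated correlation, camera called 0 lists for a, not 2. Of the 17 list and pair combinations, 12 also stood apart at 95% identity (all but both cytokinin ones, abscisic acid in hermaphrodite over monoecious and over gynoecious, and flavonoid in andromonoecious over hermaphrodite) and 17 with size factors; of the 20 that stood apart at 95% identity, 8 were new: cell cycle in andromonoecious over monoecious and over gynoecious, defence in hermaphrodite over monoecious, flavonoid in gynoecious over monoecious, sugar in hermaphrodite over monoecious and over gynoecious and in andromonoecious over gynoecious, and transposon-related in hermaphrodite over gynoecious; the cytokinin median of gynoecious over monoecious reversed to 0.01. An absolute log2 ratio of at least 3 left 252 genes (hermaphrodite over andromonoecious), 331 (gynoecious over hermaphrodite), 564 (gynoecious over monoecious) and 336 (monoecious over andromonoecious) of the authors' lists; 2 removed none. Of 274 further values for named genes and lists, 238 kept their direction and either stayed within their error (genes) or still stood apart (lists). With library totals, median log2 ratios were taken over unigenes with at least 50 reads in total. They were 0.109 (gynoecious over monoecious), 0.161 (hermaphrodite over monoecious), -0.172 (andromonoecious over gynoecious) and -0.168 (andromonoecious over hermaphrodite), against at most 0.061 with TMM. Genes with few reads, such as the ACC synthases, are limited by depth.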

Other observations

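The tests of the scaling, of another organism and of the stamens were chosen only after the result was seen. Each library had its own set of unigenes apart from the other 3, singled out after their values were seen. In the monoecious library, the transcriptional corepressor SEUSS Unigene16402, known from floral organ identity, had 21 reads against 205 gynoecious, 132 hermaphrodite and 112 andromonoecious. The growth regulator TCP15 Unigene36262 had 0 monoecious reads against 94, 20 and 7. The cell cycle factor E2FA Unigene46209 had 4 gynoecious reads against 58 monoecious, 109 hermaphrodite and 128 andromonoecious, and L-ascorbate oxidase Unigene8004 had 0 against 40, 82 and 50. In the hermaphrodite library, the glucose-6-phosphate translocator had 0 reads for Unigene39765 (54 monoecious, 170 gynoecious, 131 andromonoecious) and 2 for Unigene39764, and Soluble inorganic pyrophosphatase Unigene50067 had 0 against 41, 40 and 47. In the andromonoecious library, fatty acid 2-hydroxylase Unigene2800 had 4 reads against 58, 31 and 62.

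The gynoecious library alone was at least 4-fold lower than all others at 795 unigenes, against 290 for the monoecious, 110 for the hermaphrodite and 88 for the andromonoecious library. Depth is argued against because the libraries held nearly equal numbers of recovered reads, 25.05 to 26.55 M. Thinning therefore changed little (771 unigenes) and is no separate evidence. The scaling is argued against because the TMM factors, 0.928 to 1.061, are small beside a 4-fold difference. For the same reason library totals changed little (745). Reads of another organism in the other 3 libraries are argued against as the whole source. Of these unigenes 22.5% matched a melon CDS, while random sets with like read numbers gave 19.8% (range 17.2 to 22.8%). Most of these unigenes had no match, and a match can be as short as 25 nt, so a part from another organism stays open. The lack of stamens in gynoecious flowers may be a source, but the pollen and anther list, with 7 unigenes, had a median log2 ratio of 0.44 over the mean of the others and is too short to decide. The make-up of the bulk, in lines and in tissues, stays open and was not tested.

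Unigene44707 and Unigene44708, called in opposite directions for the a locus, carry consecutive numbers. Among 139 unigenes with at least an 8-fold a locus difference and no overlap, this was 1 such pair, while 5 consecutive pairs had the same direction.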
